A study of Brassica oleracea with 15 samples.

How the data were processed

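Hypocotyl flanks of Brassica oleracea were measured on 15 arrays, 1 per sample, and the series' design text describes the samples as biological, each group in triplicate. Per the labels' protocols, each pool came from about 100 seedlings, flank sections were about 1 cm long and held the outer part of the hypocotyl, and about 20 ug of total RNA was made into biotin-labelled cRNA. The deposited values are intensities, the Affymetrix signal of each probe set on a linear scale, made with GCOS 3.0, per the submitters' processing notes. The settings of that program and the date of each array are not given in the sources used here. In the deposited table the mean of each array after leaving out the lowest and highest 2% of probe sets was 500, so the authors' values had been scaled per array; no detection calls were used here. The table held no columns of values other than those of the 15 samples. The highest share of identical values between 2 arrays was 0.09%, so no array was counted as a duplicate.

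Arabidopsis probes were hybridised with Brassica cRNA, so mismatches lower the signal of some probe sets and a gene whose transcript does not match its probes is not measured. Gene names came from the annotation table of the array, in which 13513 probe sets carried 1 gene symbol and 503 several; 8794 were not listed and are unnamed here. No gene was named from a probe set with several symbols. Names such as AT5G45670 are Arabidopsis loci, and no coordinates were used.

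Values at or below 0 (1 value) were set to the smallest positive value, 0.4, and log2 was taken with no offset. The 64 Affymetrix control probe sets were left out, and probe sets were kept when their mean log2 signal was at or above the median of all, 8.28, which left 11371, of which 6284 carried 1 gene symbol. A linear model with 5 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with 10 residual degrees of freedom shared by all groups. Adjusted p values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. Log2 changes are given with the standard error of the moderated fit. The median residual SD of log2 signal was 0.35 for the tested probe sets and 0.89 for those left out as dim. The fit was tested on simulated data with normal noise, at the SD of each probe set as moderated along the intensity trend in the real arrays. For the combined flank comparison 70 of 100 changes of 1 log2 unit and 94 of 100 changes of 2 log2 units were recovered, with 11 false calls among 11371 probe sets. For blue light against the control 54 and 90 of 100 were recovered, with 11 false calls. The simulated probe sets were independent of each other, unlike real genes, and the changes of both sizes were planted together. Their SDs followed the intensity trend that the fit assumes, which may raise recovery. Many changes at once ease the adjusted threshold, so recovery in the real data may be lower.

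The comparisons, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined. In the flank comparisons and those of each stimulation with the control, the rule named up to 10 genes higher and 10 lower among single-gene probe sets past the threshold, by size of change; elsewhere up to 3 each way; and where none passed, the 3 of smallest p each way. Of each list, up to 4 members past the threshold were named, or up to 3 of smallest p where none passed, and a gene with several probe sets was given by its brightest. RCA in the comparisons of gravity with the control and of shaded with lit flank was given outside that rule, chosen after its values were seen. The interaction of WES1, nad4 in gravity and in the lit, bottom and top flank against the control, and rpl16 in blue light against gravity met the rule only through a name match or lists added after the data were seen. The 20 lists held 373 genes, of which 51 matched a named probe set and 29 were tested; 4 symbols that belong to another gene in the table were left out by chromosome, a check set once the table was seen, and WES1 and STZ were matched as other names of GH3.5 and ZAT10, after the values of WES1 were seen. Only the expansin list (8 tested), the XTH list (6) and the photosynthesis list (6) had the minimum of 3 tested probe sets; the other 17, among them the Aux/IAA, SAUR, brassinosteroid, gibberellin and ethylene lists and the markers of vascular and epidermal tissue, were not analysed here as lists. Lists were tested with limma's camera with its preset correlation and again with a correlation estimated from the data, adjusted over the 3 lists. Lists of organelle-encoded genes and families of genes that share a symbol stem were added after the data were seen. Values per array were compared with two-sided exact permutation tests.

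Each comparison was repeated with quantile normalization, with arrays centred on their medians, with no filter, with the brightest 30% of probe sets, with an offset of 106.5 before log2, with the arrays of the compared groups only, without the intensity trend, with array weights, with the replicate number in the model, and leaving out each array in turn.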

Results

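Gene expression was measured in flank sections of the hypocotyl, the stem of the seedling below its cotyledons, of dark-grown Brassica oleracea seedlings that were 3 days old. Seedlings were given 2 h of blue light from one side, 2 h of gravity stimulation, or a mock stimulation, and opposite flanks were pooled apart. The 15 arrays fell into 5 groups of 3: the shaded and the lit flank after blue light, the bottom and the top flank after gravity stimulation, and control flanks. In both bending responses the shaded or bottom flank is the one that elongates more, and these are called the elongating flanks here. The cRNA was hybridised to Arabidopsis ATH1 arrays, so a signal depends on how well the Brassica transcript matches the Arabidopsis probes, and levels of different genes were not set against each other. Every array had a trimmed mean signal of 500, and the 11371 brighter probe sets were tested. The number of arrays, 3 per group, limits the precision. Correlations of log2 signal between arrays had a median of 0.841 within groups, 0.836 between opposite flanks of one stimulation and 0.824 between stimulations. The first principal component, with 14% of the variance, placed all 6 blue light arrays below 0 and all 6 gravity arrays above it.

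The first comparison asked which transcripts differed between the flanks that elongate and the opposite flanks, over both stimulations. WES1, the Arabidopsis GH3.5 gene whose enzyme joins auxin to amino acids, was 1.92-fold higher in the elongating flanks (log2 change 0.94, SE 0.12, adjusted p = 0.0057, limma, n = 6 and 6). Its mean signal was 2405 ± 378 (SD, n = 3) in the shaded and 1396 ± 203 in the lit flank, 2315 ± 24.6 in the bottom and 1081 ± 118 in the top flank, and 1375 ± 221 in the control. HAT2, an auxin-inducible homeodomain-leucine zipper gene, was 2.35-fold higher (log2 change 1.23, SE 0.20, adjusted p = 0.017), and AT5G45670, of the GDSL esterase/lipase family, was 2.23-fold higher (log2 change 1.15, SE 0.18, adjusted p = 0.016). The control signals of AT5G45670, 7064.6 to 17294.8, overlapped those of the elongating flanks. They lay above every lit flank array (at most 3613.3) and every top flank array (at most 6227.6). AT2G19880, which encodes a ceramide glucosyltransferase, rose by 0.90 and AT2G39130 by 0.71 on the log2 scale. Among the genes that fell were AT1G20070 with a log2 change of -1.60, the peroxidase gene PRXR1 with -1.08, AT4G27450 with -1.07 and AT4G38810 with -0.91, at adjusted p values of 0.030, 0.030, 0.030 and 0.043. For WES1, HAT2, AT5G45670 and AT2G19880, every elongating flank array lay above every opposite flank array.

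**Figure D1:**
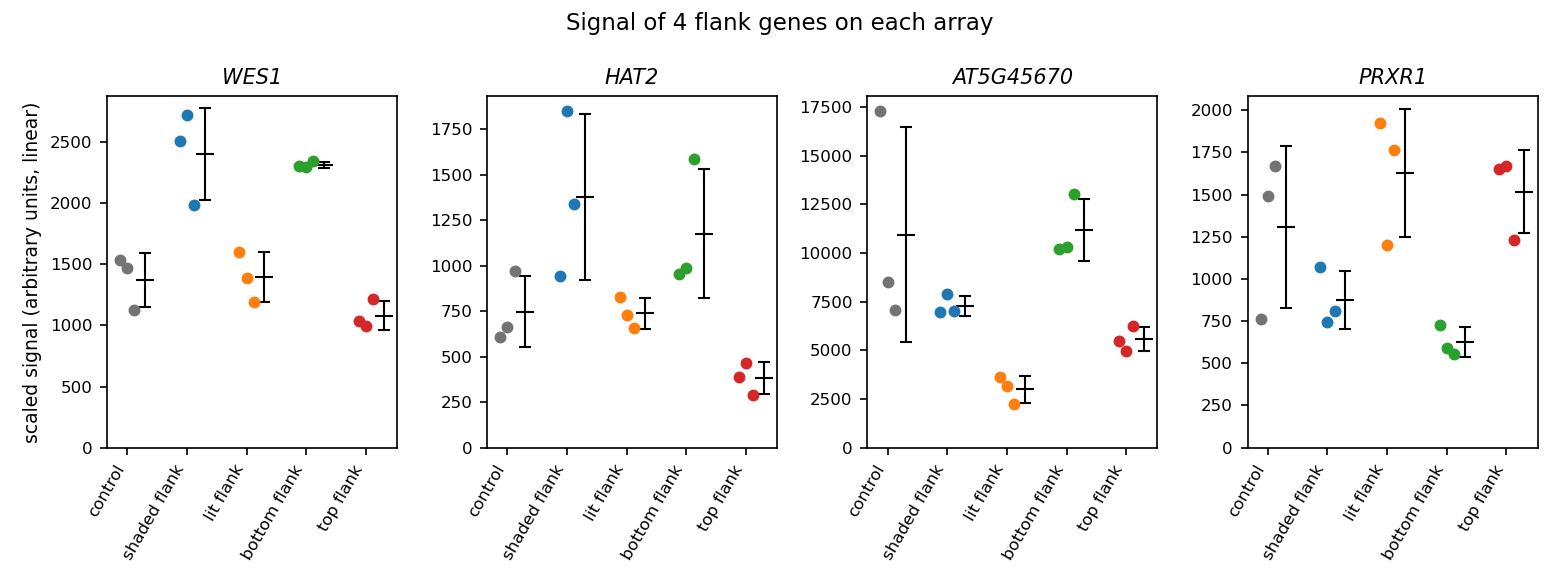
Scaled signal (linear, arbitrary units) of 4 genes on each of the 15 arrays, by group; each point is 1 array, and the bars give the mean and SD of 3 arrays. WES1 averaged 2405 and 2315 in the shaded and bottom flanks and 1396 and 1081 in the lit and top flanks, and PRXR1 was lower in the shaded and bottom flanks.

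In all, 27 of the 11371 probe sets passed the threshold in this combined flank comparison, 17 higher and 10 lower in the elongating flanks, and 9 of them carried the name of a single gene. None of the 6 tested genes of the xyloglucan endotransglucosylase/hydrolase (XTH) list, cell wall enzymes, passed the threshold over all genes, and 4 did so adjusted over the list alone. XTH16 had a log2 difference of 0.99 (adjusted p = 0.17) and XTH32 one of -0.77 (adjusted p = 0.15), so the list held members on both sides, with 5 higher and 1 lower. Its camera test gave an adjusted p = 0.0458 towards the elongating flanks, and an adjusted p = 0.239 with an estimated correlation. With the preset correlation the list no longer passed without shaded flank replicates 1 and 2 (adjusted p = 0.0902 and 0.125), lit flank replicates 2 and 3 (0.0977 and 0.0735), bottom flank replicates 1 and 3 (0.176 and 0.0775) or top flank replicates 1 and 2 (0.098 and 0.0862). The 6 tested photosynthesis genes all had lower estimates in the elongating flanks, with a median log2 difference of -0.31 and an adjusted p = 0.0235 by camera, which became an adjusted p = 0.239 with an estimated correlation. PSBY had the largest difference, -0.50. That list no longer passed without shaded flank replicate 2 (adjusted p = 0.0632), bottom flank replicate 2 (0.0763, median -0.17) or top flank replicate 1 (0.098, median -0.19, with 1 of the 6 then higher). None of these 6 passed over all genes, and 0 did so adjusted over the list alone. The 8 tested expansins, proteins that loosen cell walls, had a median log2 difference of 0.05 (camera adjusted p = 0.865), with EXPA8 at 0.35 and EXPB3 at -0.59. Of these genes 0 passed over all genes and 2 adjusted over the list alone. The count of 27 became 4 without the intensity trend in the variance model and 15 without the filter on dim probe sets, while WES1 and AT2G19880 kept their calls under every alternative and on leaving out any 1 array. HAT2, AT5G45670 and AT2G39130 lost theirs without the trend and without shaded flank replicate 2, lit flank replicate 3 or bottom flank replicate 3 (adjusted p up to 0.11). The 4 named genes that fell lost theirs without the trend, without the filter and without at least 8 of the 12 arrays taken singly (adjusted p up to 0.13). It was 16 and 5 without shaded flank replicates 1 and 2, 16 and 6 without lit flank replicates 2 and 3, 12 and 6 without bottom flank replicates 2 and 3, and 12 without top flank replicate 1.

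Within the blue light stimulation alone, shaded against lit flank, no probe set passed the threshold in limma, with 598 at an unadjusted p under the same threshold where 569 were expected by chance. The genes of smallest p that did not pass were AT5G45670, WES1 and AT3G51410 on the higher side, with log2 differences of 1.31, 0.78 and 0.68, and AT3G42530, AT5G13950 and AFR on the lower side, with -2.37, -1.46 and -1.26. Their adjusted p ran from 0.27 to 0.45. In simulated data, 35 of 100 changes of 1 log2 unit and 84 of 100 changes of 2 log2 units were recovered in this comparison. Those data had independent probe sets, SDs that followed the trend of the fit and many changes planted together, so recovery may be lower where few genes change. None of the XTH, photosynthesis or expansin lists passed in it (camera adjusted p 0.13, 0.13 and 0.91), with 3, 0 and 0 members past the threshold adjusted over the list alone. The XTH list passed without shaded flank replicate 3 (adjusted p = 0.0345; adjusted p = 0.158 with an estimated correlation, and 0.481 over all arrays). The count was 2 without shaded flank replicate 1 and 1 and 3 without lit flank replicates 1 and 3. With stimulation by number as a replicate block, a pairing the labels do not give, it was 2, both higher, one of them AT5G45670.

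After gravity stimulation, bottom against top flank, WES1 was 2.15-fold higher in the bottom flank (SE 0.18 on the log2 scale, adjusted p = 0.048, limma) and was the only named gene among 4 probe sets that passed, 3 higher and 1 lower. HAT2, at a log2 difference of 1.61, missed the threshold (adjusted p = 0.055). The camera adjusted p was 0.224 for the XTH list, 0.0587 for photosynthesis and 0.733 for expansins, and 3, 1 and 0 members passed adjusted over the list alone. The photosynthesis list passed without bottom flank replicate 1 (adjusted p = 0.00489) and without top flank replicates 2 and 3 (0.0173 and 0.0329), and the XTH list without bottom flank replicate 2 (0.0385). With an estimated correlation these became 0.267, 0.44, 0.382 and 0.0935, and over all arrays both lists had an adjusted p = 0.383. The call of WES1 was lost on leaving out any 1 of the 6 arrays, with adjusted p up to 0.18, and the count was 0 under quantile normalization, with centred arrays, without the filter and without the trend. With only the arrays of the compared groups the count was 1, and with stimulation by number as a replicate block 17. Of these, 0 and 2 were among the 4, so WES1 was lost with only the compared groups. Without bottom flank replicates 1, 2 and 3 it was 7, 1 and 0, and without top flank replicates 1, 2 and 3 it was 1, 0 and 2.

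Whether the flank difference depended on the stimulation was tested as an interaction, and no probe set passed (limma). At an unadjusted p under the threshold there were 383, where 569 were expected by chance. BAT1 had the largest estimate on the higher side among the genes of smallest p, 2.29, followed by AT5G51280 at 1.99 and AT1G67850 at 1.42. AT1G47380, CML42 and AT4G22960 had -1.55, -1.57 and -1.20, and all 6 had an adjusted p of 1. For WES1 the interaction was -0.32 (SE 0.25) and for HAT2 -0.76 (SE 0.40). In the combined flank comparison their SEs were smaller, 0.12 and 0.20, and recovery of interactions was not simulated. The lack of calls therefore does not show that flank differences were the same in both stimulations. Without top flank replicate 1 the count was 1. Across the tested probe sets, which are not independent replicates, the 2 flank differences had a Pearson r of 0.173 and a Spearman rho of 0.159. They share no arrays, and 1 of 100 relabellings within stimulations, the real one, gave an r as large (permutation p = 0.01, one-sided, the smallest that 100 relabellings can give).

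**Figure D2:**
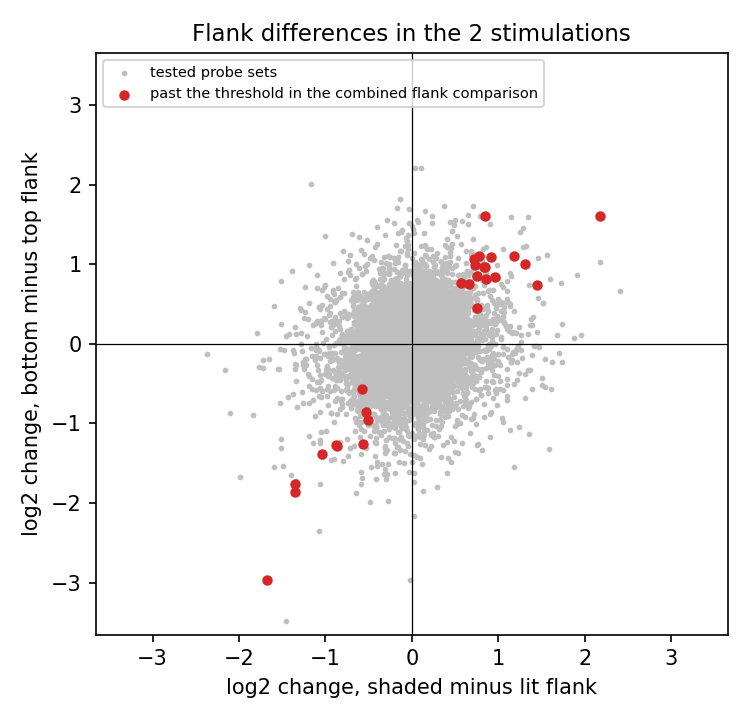
Log2 change of each of the 11371 tested probe sets, shaded minus lit flank on the x axis against bottom minus top flank on the y axis; red points are the 27 probe sets past the threshold in the combined comparison, which averages both axes, so that their place near the diagonal follows from how they were chosen. Over all points the Pearson r is 0.173.

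Both blue light flanks were compared with the control as the mean of the 2 flanks, so a change in 1 flank alone also enters this comparison. The labels give no dates or seed lots, so a difference between batches of seedlings or arrays cannot be told apart from the light treatment. Among the genes that rose, PRK, phosphoribulokinase, was 2.37-fold higher (log2 change 1.24, SE 0.22, adjusted p = 0.031) and RCA, Rubisco activase, 2.08-fold higher (log2 change 1.06, SE 0.20, adjusted p = 0.036). RCA had a mean signal of 2207 ± 307 in the lit flank, 1997 ± 302 in the shaded flank and 1028 ± 277 in the control (SD, n = 3). AT3G09470 rose by 1.84, AT1G01800 by 1.15, HCF101, needed for photosystem I assembly, by 1.02, and AT5G58330, a NADP-dependent malate dehydrogenase gene, by 0.80. Among those that fell, nad4, a mitochondrial complex I subunit, changed by -1.09 (SE 0.16, adjusted p = 0.011), and the plastid genes psaI, accD and petA by -1.31, -1.21 and -1.11. AT5G53880, AT3G62360, AT5G45670 and AT3G14410 changed by -1.71, -1.61, -1.13 and -0.79. For AT5G45670 the change was -1.78 in the lit flank, and its shaded flank signals, 6968.7 to 7878.6, overlapped the control signals.

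In total 25 probe sets differed, 10 higher and 15 lower, and under quantile normalization the split was 19 higher and 11 lower. Without control replicate 3 it was 43 higher and 18 lower. Of the 6 tested photosynthesis genes all had higher estimates, 1 (RCA) passed over all genes and 1 adjusted over the list alone, and the median log2 change was 0.62 (camera adjusted p = 0.000856; adjusted p = 0.194 with an estimated correlation). Without control replicate 1 the list did not pass (median 0.26, camera adjusted p = 0.0653), and without control replicate 3 its median was 0.99. Neither the XTH list (median -0.10, mean 0.11, adjusted p = 0.557) nor the expansins (median -0.04, adjusted p = 0.557) passed, with 2 and 0 members past the threshold adjusted over the list alone. Beside these, the 3 prime minus 5 prime log2 difference of 3 control transcripts, a measure of RNA and cDNA length, was -0.31 ± 0.15 (SD, n = 6) on the blue light arrays and 0.06 ± 0.30 (n = 3) on the control arrays (two-sided exact permutation p = 0.0238, and 0.119 after adjustment over 5 comparisons). Its level also depends on how the Brassica transcripts match these Arabidopsis probes. GAPDH lay between -3.69 and -2.08 over all arrays and actin between 1.16 and 2.62, so only differences between arrays were read. Without control replicate 1 the difference was -0.20 (exact p = 0.143). The count was 5 and 9 without shaded flank replicates 1 and 2, 1, 3 and 61 without control replicates 1, 2 and 3, 9 without the intensity trend and 60 with array weights. The 1 probe set called without control replicate 1 was not among the 25, so that all 14 named genes lost their calls there, nad4 at an adjusted p = 0.096, PRK at 0.20 and RCA at 0.21. Of the 14, nad4 alone kept its call without any other single array, and nad4 alone kept it under every other alternative. PRK and RCA lost theirs also without control replicate 2 (adjusted p = 0.16 and 0.14), shaded flank replicates 1 and 2 and lit flank replicate 2, PRK without lit flank replicate 3 and RCA without lit flank replicate 1.

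Both gravity flanks were likewise compared with the control as the mean of the 2 flanks, so a change in 1 flank alone also enters this comparison. It used the same 3 control arrays as that of blue light, so the results of both are not independent. Batches of seedlings or arrays cannot be told apart from the stimulation here either. The plastid ribosomal protein gene rpl14 had a signal of 15920 ± 1860 in the control, 852 ± 84.1 in the bottom flank and 803.8 ± 318 in the top flank (SD, n = 3), a log2 change of -4.30 (SE 0.23, adjusted p = 1.3e-08), and rpl16 changed by -1.78 (SE 0.17, adjusted p = 8.5e-05). Other genes that fell were AT3G23940, a dihydroxy-acid dehydratase gene of branched-chain amino acid synthesis, by -1.66, AT1G25230 by -1.52, AT2G42490, a copper amine oxidase gene, by -1.23, and AT4G14160 by -1.07. Smaller falls were measured for AT1G12000, AT1G15370, AT5G15950 and AT4G25740, between -0.96 and -0.87, and for nad4, at -0.84. AT4G26870, of the class II aminoacyl-tRNA synthetase family, was 5.07-fold higher (log2 change 2.34, SE 0.24, adjusted p = 9.1e-05). AT5G61340, the terpene synthase gene AT3G25810, AT2G13160 and AT5G05320 rose by 2.74, 2.26, 1.94 and 1.68, and AT3G09470, ALDH22A1, AFR, RTE1 and AT1G01800 by 1.56, 1.52, 1.48, 1.38 and 1.16. AT3G09470, AT1G01800 and nad4 differed from the control in the same direction after blue light, as a shift of the shared control arrays would also give.

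**Figure D3:**
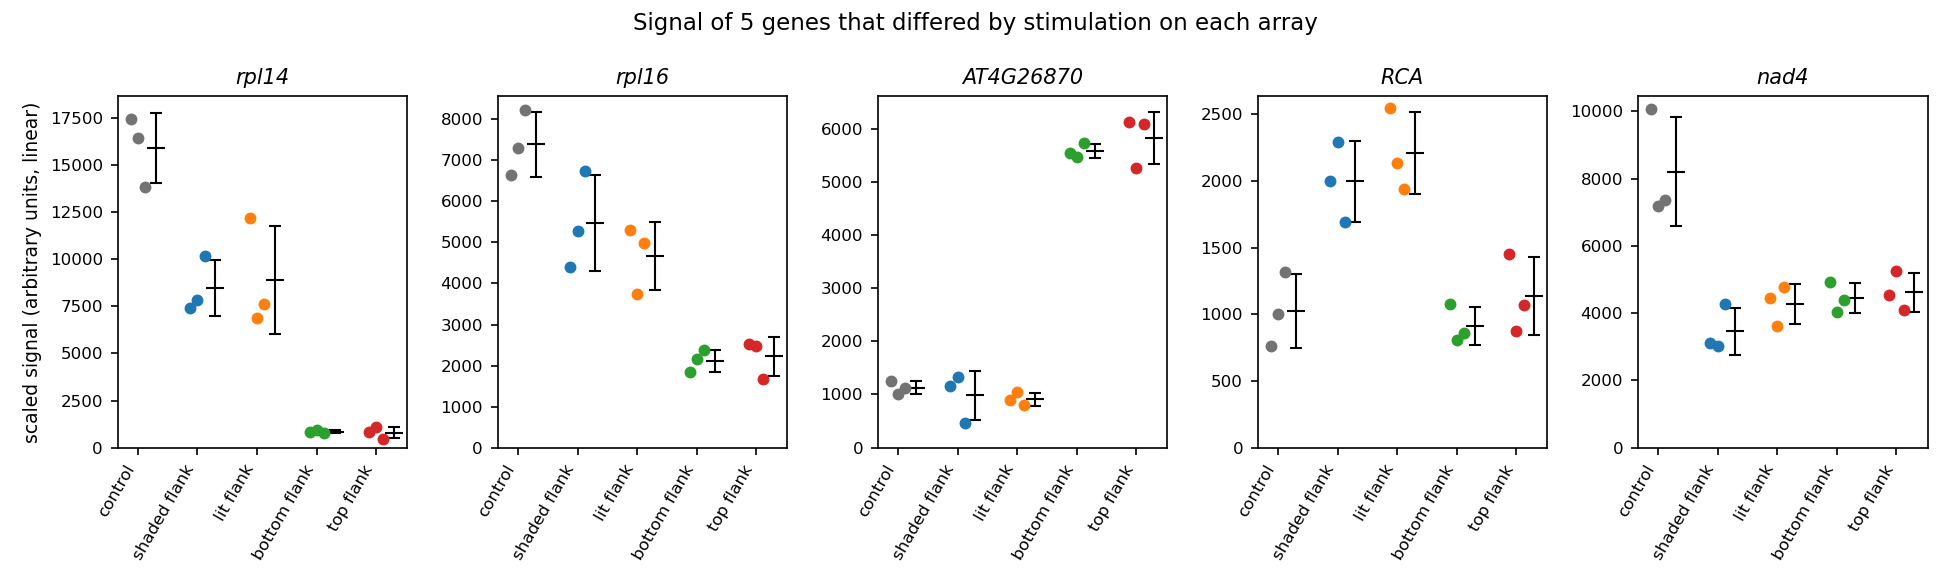
Scaled signal (linear, arbitrary units) of 5 genes on each of the 15 arrays, by group; each point is 1 array, and the bars give the mean and SD of 3 arrays. All 6 gravity arrays had rpl14 signals between 477.7 and 1112, below every control array, and nad4 was lower in all 4 stimulated groups than in the control.

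In this comparison 83 probe sets passed, 42 higher and 41 lower (43 and 39 under quantile normalization, 39 and 47 with centred arrays). The photosynthesis, XTH and expansin lists gave camera adjusted p values of 0.412, 0.24 and 0.412, with 0, 1 and 0 members past the threshold adjusted over the list alone. RCA had a log2 difference of 0.00, XTH20 one of 0.73 and EXPA9 one of -0.56, none of them past the threshold. The 3 prime minus 5 prime difference was -0.17 ± 0.11 (n = 6) on the gravity arrays (two-sided exact permutation p = 0.119 against the control). Its difference from the control was -0.06 without control replicate 1 (exact p = 0.536) and -0.35 without control replicate 3 (exact p = 0.0357). The calls of rpl14, rpl16, AT4G26870, AT3G23940 and AT4G14160 were kept under every alternative and on leaving out any array. Each of the other named genes past the threshold lost its call without at least 1 array, AT1G25230 and AT2G42490 without control replicate 2 (adjusted p = 0.057 and 0.06), nad4 without control replicate 1 (0.11) and AT3G25810 without any 1 of the 9 arrays (up to 0.16). The count was 55 without top flank replicate 1, 50, 30 and 47 without control replicates 1, 2 and 3, 37 without the intensity trend, 142 with the brightest 30% of probe sets and 169 with array weights.

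Each flank was also compared with the control by itself, using the same 3 control arrays each time, so that these comparisons are not independent. In the lit flank 41 probe sets differed, 18 higher and 23 lower (18 and 14 under quantile normalization, 11 and 24 with arrays centred on their medians). The count was 1 with only the arrays of the compared groups, 13 without the trend, 17 without the filter, 77 with the brightest 30% of probe sets and 93 with array weights. XTH32 was 2.94-fold higher there (log2 change 1.55, SE 0.26, adjusted p = 0.019), AT3G09470 and HCF101 rose by 2.04 and 1.14, and AT3G62360, AT5G45670 and AT2G28320 changed by -2.01, -1.78 and -1.78. XTH32 lost its call with only the compared groups (adjusted p = 0.07), without the trend (0.066), without lit flank replicate 3 (0.077) and without control replicates 1 and 2 (0.10 and 0.061). None of the named genes kept its call under every alternative, and AT5G45670 alone kept it on leaving out any array. RCA was the 1 of the 6 photosynthesis genes that passed in the lit flank, at 1.13 (list median 0.75, camera adjusted p = 0.000443; adjusted p = 0.166 with an estimated correlation). Without control replicate 1 the list median was 0.40 (camera adjusted p = 0.0199; adjusted p = 0.40 with an estimated correlation) and the call of RCA was lost (adjusted p = 0.19), as it was without control replicate 2 or any 1 lit flank array. In the shaded flank nad4 was the only probe set that passed, at -1.25 (adjusted p = 0.034), with 842 probe sets at an unadjusted p under the threshold. The fall of nad4 was not particular to that flank: it also passed in the lit, bottom and top flank, at -0.93, -0.87 and -0.82 (limma adjusted p = 0.039, 0.044 and 0.043). Its call in the shaded flank was lost without shaded flank replicates 1 and 2 (adjusted p = 0.12 and 0.13) and control replicates 1 and 2 (0.12 and 0.06). It was also lost under quantile normalization (adjusted p = 0.082), without the filter (0.073), with only the compared groups (0.26), without the trend (0.14) and with the replicate number in the model. Without shaded flank replicate 1 or control replicate 1 the 1 probe set that passed was another one, higher in the shaded flank. The photosynthesis list was higher in the shaded flank, with 6 of 6 estimates above 0 (5 with arrays centred on their medians) and a median of 0.49 (camera adjusted p = 0.0155; adjusted p = 0.327 with an estimated correlation). Of its genes 0 passed over all genes and 1 adjusted over the list alone. That list did not pass without control replicate 1 (median 0.10, camera adjusted p = 0.222) or without shaded flank replicate 3 (adjusted p = 0.0866), and its median was 0.86 without control replicate 3. RCA had a log2 change of 0.98 in the shaded flank (SE 0.23, adjusted p = 0.24, limma), beside 1.13 in the lit flank. Its shaded minus lit difference was -0.15 (SE 0.23), and no probe set passed in that direct comparison. A call in 1 flank and not in the other therefore does not show a difference between the flanks. In the bottom flank 49 differed, 19 higher and 30 lower, among them AT4G26870 and ALDH22A1 at 2.31 and 1.55, DRT100, which was 2.15-fold higher, and rpl14, AT1G22885 and AT5G51280 at -4.22, -2.19 and -2.11. In the top flank 97 differed, 48 higher and 49 lower, among them AT5G55180, AT3G25810 and AT4G26870 at 2.99, 2.44 and 2.37 and rpl14, AT3G03960 and AT1G51300 at -4.38, -2.19 and -1.93 (47 higher and 40 lower under quantile normalization, 36 and 48 with centred arrays). Without top flank replicate 2 the split there was 19 higher and 63 lower. In both gravity flanks the calls of rpl14 and AT4G26870 were kept under every alternative and on leaving out any array. Leaving nad4 aside, the other genes named there lost theirs under at least 1 alternative and without at least 4 of the 6 arrays taken singly. Without control replicates 1, 2 and 3 the counts of the bottom flank were 24, 17 and 31 and those of the top flank 33, 39 and 52, the lit flank had 6 and 14 without control replicates 1 and 2, and the shaded flank had 0 and 10 without control replicates 2 and 3. They were also 19 and 12 without lit flank replicates 2 and 3, 25 and 21 without bottom flank replicates 2 and 3, 21 and 61 without top flank replicates 1 and 3, and 0 without shaded flank replicate 2.

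Blue light and gravity arrays were then compared directly, without the control. Among the named genes rpl14 differed most, 10.6-fold higher after blue light (log2 change 3.41, SE 0.18, adjusted p = 2.1e-08), with rpl16 at 1.22, AT1G16080 at 1.72 and AT3G23940 at 1.45. Lower after blue light were the terpene synthase gene AT3G25810 at -3.31, AT4G26870 at -2.66 and AT2G39630 at -1.99. RCA was 2.08-fold higher after blue light (log2 change 1.05, SE 0.16, adjusted p = 0.0028), and it was the 1 of the 6 photosynthesis genes that passed (list median 0.30, camera adjusted p = 0.0126; adjusted p = 0.398 with an estimated correlation). The list did not pass without bottom flank replicate 2 (camera adjusted p = 0.0578). In the XTH list XTH32 was higher, at 1.03, and XTH20 lower, at -0.88, while 4 members did not pass (camera adjusted p = 0.333, 4 past the threshold adjusted over the list alone). The expansin list did not pass (camera adjusted p = 0.795). There were 253 probe sets past the threshold, 114 higher and 139 lower (133 and 122 under quantile normalization, 90 and 147 with centred arrays), so that which side held more depended on the scaling. The genes RCA, XTH32, rpl14, rpl16, AT3G23940, AT3G25810 and AT4G26870 kept their calls under every alternative that tested them and on leaving out any array. AT1G16080, AT2G39630 and XTH20 lost theirs without the trend, without the filter and without 11, 10 and 7 of the 12 arrays taken singly (adjusted p up to 0.092). The count was 106 without the intensity trend, 145 without the filter, and 146, 139, 160, 132, 150 and 154 without shaded flank replicate 1, lit flank replicate 3, bottom flank replicates 2 and 3 and top flank replicates 2 and 3. Because the labels give no dates or seed lots, a difference between stimulations and a difference between batches of seedlings or arrays cannot be told apart.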

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

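Each comparison was refitted under the alternatives named with the processing; the lists of organelle-encoded genes and their tests, and list and per-array values without single arrays, were chosen after the data were seen. Of the 87 named results past the threshold, 0 changed direction in any fit, 28 kept their call under every alternative and 24 on leaving out any 1 array. Some genes are among the 87 in several comparisons. All were chosen for a small adjusted p and refitted on the same arrays or most of them, so the 0 was nearly given beforehand. The medians of the XTH, photosynthesis and organelle lists kept their direction under quantile normalization and centred arrays wherever a list passed. The causes of the differences below were not tested, except that fewer arrays, or more or fewer probe sets, enter some fits by construction. With quantile normalization the count was 0 for bottom against top flank (4 as reported) and 0 for the shaded flank against the control (1 as reported), and with arrays centred on their medians it was 0 for bottom against top flank. With no filter the counts were 0 for bottom against top flank, 15 for the combined flank comparison, 0, 17, 19 and 43 for the shaded, lit, bottom and top flank against the control, 11 for blue light against the control and 145 for blue light against gravity. With the brightest 30% of probe sets they were 77 for the lit flank, 57 for blue light and 142 for gravity, each against the control. With only the arrays of the compared groups they were 1 for bottom against top flank, 0, 1, 27 and 54 for the shaded, lit, bottom and top flank and 13 for blue light against the control. Without the intensity trend they were 0 for bottom against top flank, 4 for the combined flank comparison, 0, 13, 20 and 25 for the shaded, lit, bottom and top flank, 9 for blue light and 37 for gravity against the control, and 106 for blue light against gravity. With array weights they were 93 for the lit flank, 60 for blue light and 169 for gravity against the control. The offset before log2 moved no count by more than 1.5 times.

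The labels do not say whether the replicate numbers pair the samples, and the samples were treated as unpaired because not every correlation was above 0.1: the deviations of same-numbered shaded and lit flanks correlated at 0.13, 0.15 and 0.04, and those of bottom and top flanks at 0.06, 0.00 and -0.02. As a hint from the data only, the own number correlated best in 3 of 3 shaded and lit pairs and 1 of 3 bottom and top pairs. Same-numbered arrays of different stimulations, or of a stimulation and the control, correlated at -0.08 to 0.04. The values of 0.13 and 0.15 lay above that range, so a pairing of shaded and lit flanks remains possible. With the number as a replicate block over all groups the counts were 0, 5 and 19 for shaded against lit, bottom against top and the combined flank comparison, 0, 22, 39 and 87 for the shaded, lit, bottom and top flank against the control, 11 and 88 for blue light and gravity against the control, and 242 for blue light against gravity. With stimulation by number as a replicate block they were 2 for shaded against lit, 17 for bottom against top and 45 for the combined comparison, 24 of which were among its 27; 2 of the 4 reported for bottom against top were among the 17. Both probe sets of shaded against lit were higher, one of them AT5G45670 (log2 change 1.31, adjusted p = 0.027), and in the combined comparison XTH32 and XTH16 passed (adjusted p = 0.021 and 0.048).

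On leaving out 1 array at a time, counts ran from 0 to 3 for shaded against lit, 0 to 7 for bottom against top, 5 to 29 for the combined flank comparison, 0 to 1 for the interaction, 0 to 10, 6 to 51, 17 to 42 and 21 to 82 for the shaded, lit, bottom and top flank against the control, 1 to 61 for blue light and 30 to 99 for gravity against the control, and 132 to 252 for blue light against gravity. Among the named genes that had not passed, PSAN in gravity against the control was reversed in sign at -0.01 without bottom flank replicate 1 and at -0.46 without control replicate 1, its lowest value, with 0.72 as the highest. LHCB4.1 was reversed at -0.08 without control replicate 1, its lowest, with 0.92 as the highest. Camera adjusted p ran from 0.034 to 0.32 for the XTH list in shaded against lit, 0.038 to 0.74 in bottom against top and 0.011 to 0.18 in the combined comparison. For photosynthesis it ran from 0.0049 to 0.41 in bottom against top, 0.0028 to 0.098 in the combined comparison, 2.7e-05 to 0.065 in blue light against the control, 0.0022 to 0.058 in blue light against gravity and 0.00049 to 0.22 in the shaded flank against the control. The change of the 25S ribosomal RNA probe set in blue light against the control ran from -0.46 to 0.20 and that of 5S from -0.03 to 0.71.

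With an estimated correlation, camera adjusted p became 0.24 for both the photosynthesis and the XTH list in the combined flank comparison, 0.19 for photosynthesis and 0.087 for plastid-encoded genes in blue light against the control, 0.33 and 0.17 for photosynthesis in the shaded and lit flank against the control, and 0.40 and 0.15 for photosynthesis and plastid-encoded genes in blue light against gravity. With no filter it was 0.052 for the XTH list in the combined comparison, and for photosynthesis in bottom against top flank it was 0.039 with quantile normalization and the preset correlation, against 0.0587 on the deposited scale and 0.383 there with an estimated correlation. The median residual SD of log2 signal was 0.89 for the dim probe sets left out, against 0.35 for those tested.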

Other observations

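The tests on rpl14 and rpl16, the 5S ribosomal RNA value, all list and per-array values without single arrays, the lists of organelle-encoded genes and the families by symbol were chosen after the results were seen. Of 67 tested plastid-encoded genes, 60 had lower estimates in the blue light flanks than in the control, with a median log2 difference of -0.43; 3 of them fell (psaI, accD and petA) and 14 passed adjusted over the list alone (camera adjusted p = 6.94e-14; adjusted p = 0.0874 with an estimated correlation). Of 12 mitochondrion-encoded genes 10 had lower estimates, with a median of -0.48, and nad4 fell (adjusted p = 2.69e-06; adjusted p = 0.0107 with an estimated correlation). Averaged per array, the mitochondrion-encoded genes differed by -0.45 on the log2 scale (6 against 3 arrays, two-sided exact permutation p = 0.0119, the smallest possible, 0.0298 adjusted over 5 comparisons), and the plastid-encoded genes differed by -0.41 (exact p = 0.0476, 0.211 adjusted). Without single arrays these ran from -0.48 to -0.41 (exact p up to 0.0357) and from -0.48 to -0.31 (exact p up to 0.107, without shaded flank replicate 1 or 2 or any control array), and both lists kept their camera calls in blue light against the control and against gravity. Against gravity, blue light arrays had a median of -0.47 for the mitochondrion-encoded genes, with cox2, cox1 and orfX at -1.25, -0.75 and -0.53, all past the threshold, which cox1 and orfX lost without the intensity trend, without the filter and without 9 and 7 of the 12 arrays taken singly, with adjusted p up to 0.10 (list adjusted p = 4.96e-05; adjusted p = 0.0241 with an estimated correlation). For the plastid-encoded genes the median was -0.33, with 14 that fell, among them psaI and atpH at -1.20 and -0.76, and 2 that rose, rpl14 and rpl16 (adjusted p = 1.48e-09; adjusted p = 0.155 with an estimated correlation).

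Among 23 families of genes that share a symbol stem, the beta-tubulin genes stood lower in blue light than in gravity arrays, with a median log2 difference of -0.51 over 5 genes and all 5 estimates below 0, under quantile normalization and with centred arrays too (camera adjusted p = 0.0268; adjusted p = 0.426 with an estimated correlation); TUB7 fell, at -0.51. The family did not pass without shaded flank replicate 2, lit flank replicate 2, bottom flank replicate 3 or top flank replicate 2 (adjusted p = 0.0612, 0.0894, 0.158 and 0.0541). No other family passed in that comparison, and none in a comparison of opposite flanks or the interaction. Against the control the rpl family, 7 genes of the plastid-encoded list, passed towards lower signals in all 6 comparisons (adjusted p from 0.000438 to 0.043), with a median of -0.21 but a mean of -0.92 in gravity, where rpl14 and rpl16 carry it. The nad family, 6 mitochondrion-encoded probe sets, passed lower in the shaded flank, the lit flank and blue light (adjusted p = 0.0199, 0.0275 and 0.0133), and the beta-tubulins in the lit flank (0.0275). Their medians kept direction under both scalings, and with an estimated correlation none passed (lowest adjusted p 0.429). The calls in the shaded flank were lost without shaded flank replicates 1 and 2 and control replicates 1 and 3 (adjusted p up to 0.461), and that in the bottom flank without bottom flank replicates 1 and 2 and control replicates 1 and 3 (up to 0.18). Those in the lit flank were lost without lit flank replicate 2 and control replicate 3, for nad and the beta-tubulins also without control replicate 1 and for nad without lit flank replicate 3 (up to 0.128). That of nad in blue light was lost without control replicate 1 (0.0602). WES1 and HAT2, members of lists too short to be tested as lists, rose in the combined flank comparison; of the other tested members of such lists none passed: GH3.9 had -0.02, WAG2 of auxin transport 0.02, YUC2 and YUC4 of auxin synthesis 0.01 and 0.04, DFR of flavonoid synthesis -0.03, PORB -0.08 and the clock gene GI -0.20. None of the 7 matched Aux/IAA genes was bright enough to be tested.

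As a hypothesis, the low signals of rpl14 and rpl16 in the gravity flanks (log2 changes of -4.30 and -1.78 against the control) may have a source specific to these probe sets. The other 65 tested plastid-encoded genes had a median of -0.04 (95% bootstrap interval over genes -0.14 to 0.02, and -0.11 to 0.04 without single arrays), which argues against a lower share of plastid RNA as the cause. That interval does not measure the spread between arrays. Averaged per array, the plastid-encoded genes with rpl14 and rpl16 included differed by -0.1 between gravity and control arrays (two-sided exact permutation p = 0.607). The 5 other measured genes of the same plastid gene cluster, rps19, rpl22, rps3, rpl36 and rpoA, had changes of -0.27, -0.21, -0.16, 0.32 and -0.52, with a median of -0.21 (-0.31 to -0.05 without single arrays), which argues against a fall of the whole cluster. All 6 gravity arrays, of both flanks, had rpl14 below every other array. A change in the tissue after gravity stimulation, another seed lot and a difference in plastid sequence under the probes would each give that, and they cannot be told apart because the labels tie neither seed lots nor dates to the arrays. AT4G26870 also separated the gravity arrays, at 5261.6 to 6115.9, from every other array, at 458.7 to 1336.6, and AT3G23940 was lower on every gravity array. For these genes too, a change in the tissue and another seed lot cannot be told apart.

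For the lower organelle-encoded genes in blue light arrays, 3 technical explanations were tested and stay open, beside a response of the tissue to light, which was not tested. Less carry-over of RNA without poly(A) tails could lower them. The change of the 25S ribosomal RNA probe set was 0.03 (95% interval -1.01 to 1.07). That interval has the width of a normal approximation, which is too narrow for 6 against 3 arrays. The change rests on lit flank replicate 2, at 12.14, where the other blue light arrays reached at most 9.73. Without that array it was -0.46 (two-sided exact permutation p = 0.107, 5 against 3 arrays), and without any other array it was between -0.14 and 0.20. The 5S ribosomal RNA probe set, dim at a mean of 5.78 against 5.35 in the control, changed by 0.43 (exact permutation p = 0.655; -0.03 without control replicate 3 and 0.71 without lit flank replicate 2), the other way but within its spread. The 3 prime minus 5 prime difference differed by -0.37 between the blue light and control means (-0.20 without control replicate 1), with ranges that overlapped, so a difference in RNA or cDNA length remains possible. After quantile normalization the medians were -0.30 for the plastid-encoded (95% bootstrap interval over genes -0.42 to -0.21) and -0.45 for the mitochondrion-encoded genes (-0.65 to -0.25), where the bound set beforehand against scaling as the cause asked only that both stay below -0.3; the plastid median lay at that bound and was -0.19 without lit flank replicate 2, the need for its whole interval to lie below was added after the value was seen, and scaling stays open as part of the cause.

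Other splits of the arrays were refitted for each comparison. For the combined flank comparison 1 of 100 splits, the real one, gave as many probe sets as the 27 counted, with 2 as the highest of the others. For blue light against gravity 1 of 100 splits reached 253, and the highest other was 5. For blue light against the control 1 of 100 splits reached 25, with a highest other of 18, and for gravity against the control 1 of 100 reached 83, with a highest other of 74. Each of these highest values came from the 1 other drawn split that kept the control arrays together and moved arrays only between the flanks, and the highest with changed sets were 3 and 7. Counts as large were thus rare among the drawn splits, but 1 of 100 is the smallest share that 100 splits can give. Splits that mix the groups also add any real group difference to the spread, which lowers their counts. Chance is therefore not excluded by these splits. For the interaction, with a count of 0, all 100 of 100 splits gave at least as many whatever the data, with a highest other of 2, so the splits say nothing about chance. The remaining comparisons have only 10 splits each, too few for a share under 0.05. Shaded against lit gave 0 with a highest other of 1, and all 10 splits were as large, as any count of 0 makes them; bottom against top gave 4 with a highest other of 4, and 2 splits as large; the shaded flank against the control gave 1 with a highest other of 1, and 2 splits as large. For the lit, bottom and top flank against the control the counts were 41, 49 and 97 with highest others of 2, 2 and 1, and 1 split as large in each.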
